A study of Homo sapiens with 6 samples.

How the data were processed

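Total RNA of MCF-7 cells was amplified, labelled with Cy5 and hybridized to single-colour arrays, per the labels' protocols. The deposited values are intensities on a linear scale, 1 per probe and array, for 31741 probes on 6 arrays. What the authors did to the scanner signal before depositing these intensities is not given in the sources used here. Every deposited intensity was a whole number times 1 factor per array (100% of values within 0.05 of a whole number). The 2 factors of a group averaged 1.00 in each group, so the arrays had been brought together within groups and not between them. The medians of log2 intensity spanned 0.233 over the arrays. By a rule set before the data were examined (a span over 0.1), the values were quantile normalized between arrays after log2(value + 1). Before normalization the median of all probes was -0.01 from the control for betulinic acid and -0.18 for the fluorinated form. Between the compounds it was -0.16. Quantile normalization gives all arrays one distribution, so changes are relative to the signal distribution of each array. Fold changes are on the log2(value + 1) scale, which understates changes of dim probes.

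Probes were named through the platform annotation, in which 24740 probes had 1 gene symbol, 977 had several and 6024 had none. Symbols were updated through the RefSeq annotation of assembly GRCh38.p14, which changed 1948, and 70 probes kept a symbol that this table did not hold. No probe with several symbols was named. No coordinates were used. Probes in the lowest 25% by mean over all arrays (7936) were left out, leaving 23805 probes and 14888 genes. A gene was represented by its probe of highest mean.

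The tests were run in R 4.3.3 with limma 3.58.1 (lmFit and eBayes) on all 6 arrays, with 3 residual degrees of freedom, so that the groups shared one estimate of the spread. Adjusted p-values are Benjamini-Hochberg over all tested probes, with a threshold of 0.05, and were also computed over each gene list alone. The 36 gene lists (1109 genes) were fixed before the data were examined and tested with camera, with a preset correlation of 0.01 and Benjamini-Hochberg over the lists. No list passed in any comparison when camera estimated the correlation from these arrays. That form also takes its p-values from the 3 residual degrees of freedom, so these failures need not come from correlation between genes. The lists overlap, so their tests are not independent. Named genes were taken by a rule fixed at the same time. It took the 12 largest increases and the 12 largest decreases per comparison among genes past the threshold whose arrays did not overlap between groups and whose brighter group lay above the median, leaving out placeholder symbols. It added the 2 largest rises and falls of each described list and 16 genes chosen for the cells and compounds. From the latter 2 parts the text gives examples.

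The tests were checked on simulated data made from the real probes' means and spreads. For fluorinated betulinic acid against control, run on 14889 genes, 15.3% of genes changed by 0.5 on the log2 scale and 86.6% of those changed by 1 were recovered. False calls made up 3.74% of all calls. A list raised by 0.5 passed camera with the preset correlation and also with an estimated one (adjusted p = 0.0222). Few genes were changed in this simulation, and the noise was drawn independently for each probe. In the real comparison 51.8% of genes passed, so the shares recovered need not hold there. False calls from differences between cultures or whole arrays could not appear in it.

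Alternatives tried were the values as deposited, median centring, no filter on dim probes and a 50% filter, eBayes with a trend and with a robust trend, a fit of only the groups compared, a replicate block, the mean of a gene's probes, a pseudocount of 16, and leaving out each array. For the lists they were camera with an estimated correlation, camera on ranks, and fry. Leaving out probes whose 2 arrays of a group differed by more than 1 on the log2 scale was added after seeing the data, as was the correlation of the compounds' changes with 1 control array for each.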

Results

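Gene expression was measured in MCF-7 cells, an established line of estrogen receptor-positive breast cancer cells, with single-colour oligonucleotide arrays. There were 6 arrays in 3 groups of 2. The labels list no treatment for one group, the control, and the others received 40 µM betulinic acid or 40 µM fluorinated betulinic acid for 24 h. They do not say whether the control cells received the solvent of the compounds, so each change against control may include an effect of the solvent. Betulinic acid is a pentacyclic triterpenoid of plant origin, and its derivative carries fluorine. The design allowed each compound to be set against the control cells, and the derivative to be set against the parent compound at the same dose and time. The series concerns the activity of betulinic acid against cell growth and the effect that fluorine has on it. The median deposited intensity was 735 and 719 on the control arrays, 736 and 705 on the betulinic acid arrays, and 626 and 661 on the fluorinated betulinic acid arrays. After normalization the arrays of one group correlated across probes at r = 0.994 for the controls, 0.990 for betulinic acid and 0.991 for the fluorinated form. Both arrays of a group carry one sample name in the labels, and nothing says that they came from separate cultures. The p-values of genes therefore measure only the spread between these arrays, which may be technical. Camera's p-values for the lists set the members against the other genes tested, and do not measure a spread between cultures either. Values after ± are standard errors of log2 fold changes, with n = 2 arrays per group. The number of arrays limits their precision. The genes given as largest changes were ranked only among those whose brighter group lay above the median signal of the tested probes (log2 10.47), and dimmer genes with larger measured changes are named beside them.

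With betulinic acid the metallothionein MT1X, a metal-binding protein, rose 14.6-fold (log2 3.87 ± 0.08), and its relative MT2A rose 9.65-fold (log2 3.27 ± 0.08). SLC7A11, the cystine transporter, rose 7.81-fold. The stress cytokine GDF15 rose 5.18-fold, asparagine synthetase ASNS rose 4.26-fold, and DDIT3, which encodes the transcription factor CHOP, rose 3.83-fold. The largest falls included the chemokine CXCL12 (6.33-fold lower, log2 -2.66 ± 0.12), the zinc transporter SLC39A10 (5.26-fold) and the long noncoding RNA DSCAM-AS1 (4.58-fold). NPY1R, a neuropeptide Y receptor, fell 4.04-fold, the scaffold protein gene PDZK1 3.89-fold, IGFBP5 3.81-fold, and GJA1, the gene of the gap junction protein connexin 43, 3.66-fold. On the mean of its probes IGFBP5 was at log2 -1.20.

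The other genes among the 12 largest rises with betulinic acid above the median signal were NRAD1 (4.57-fold), TSC22D3 (4.49-fold), TGFBI (3.98-fold), LCN2 (3.81-fold), STRA6 (3.46-fold) and HS1BP3 (3.22-fold). At a lower signal CHAC1 rose 3.41-fold and INHBE 5.05-fold, the latter a size that is uncertain for a reason given below. TSC22D3 encodes a glucocorticoid-induced leucine zipper protein and LCN2 encodes lipocalin 2. The remaining large falls above the median signal were of PLA2G2E (5.89-fold), HRH3 (4.50-fold), QPCTL (4.42-fold), EGR3 (3.57-fold) and NEUROD2 (3.47-fold). Leaving out control replicate 2 ended the calls of PLA2G2E (adjusted p = 0.0117 with all arrays), QPCTL (0.00892) and NEUROD2 (0.0261), as control replicate 1 did for PLA2G2E and NEUROD2 and either betulinic acid array for NEUROD2. A second probe of HRH3 and one of NEUROD2 did not pass the test, and on the mean of their probes these genes were at log2 -1.03 and -0.78.

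In all, 4969 of 14888 genes changed with betulinic acid, 2841 upward and 2128 downward (limma, Benjamini-Hochberg adjustment). Of these, 337 changed at least 2-fold, 152 upward and 185 downward. The total fell to 1174 without control replicate 1 and to 1060 without control replicate 2. Where a changed gene had a further probe that also changed, that probe went the other way in 136 of 610 cases.

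Of 31 measured genes in the list of ATF4 and the integrated stress response, the program that follows phosphorylation of the initiation factor eIF2, 24 rose with betulinic acid and 1 fell (25 and 2 adjusted over the list alone). Their median log2 change was 1.08 (camera adjusted p = 9.76e-10, and adjusted p = 0.214 with an estimated correlation). In the p53 target list 16 of 33 rose and 3 fell, and the counts adjusted over the list alone were the same (adjusted p = 0.0208, and adjusted p = 0.298 with an estimated correlation). The members that rose most were GDF15 and SESN2 (2.43-fold), which are also targets of ATF4. BTG2, also a p53 target, rose by close to as much as SESN2. Its log2 signal was 12.98 and 13.27 on the control arrays and 14.47 and 14.35 on the betulinic acid arrays. CDKN1A, the gene of the cell cycle inhibitor p21, was at log2 0.18 ± 0.11 (adjusted p = 0.270) and passed only without betulinic acid replicate 2 (log2 0.33, adjusted p = 0.0411). NRF2 target genes of the antioxidant response rose in 11 of 27 cases and fell in 2 (14 and 3 adjusted over the list alone, adjusted p = 0.0208, and adjusted p = 0.298 with an estimated correlation). HMOX1, which encodes heme oxygenase 1, rose 2.19-fold, and the peroxiredoxin gene PRDX1 fell 1.41-fold, a call lost without either control array. This list did not pass without betulinic acid replicate 1 (adjusted p = 0.0734). Among 9 metallothionein and zinc response genes 5 rose, also when adjusted over the list alone (adjusted p = 0.0208, and adjusted p = 0.336 with an estimated correlation), and with the dimmest 50% of probes left out the list did not pass (adjusted p = 0.0888).

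By the set test 7 lists were lower with betulinic acid. Of 38 measured estrogen receptor targets 23 fell and 1 rose (25 and 1 adjusted over the list alone), with a median log2 change of -0.59 (adjusted p = 7.82e-09, and adjusted p = 0.157 with an estimated correlation). CXCL12 and NPY1R fell most, while STC2, also an ATF4 target, rose 2.65-fold (log2 0.76 on the mean of its probes). The receptor gene ESR1 fell 1.64-fold and TFF1 1.42-fold, and both calls were lost without either control array. In the G1/S and DNA replication list 27 of 47 fell and 1 rose (34 and 1 adjusted over the list alone, median log2 -0.43, adjusted p = 9.76e-10, and adjusted p = 0.157 with an estimated correlation). UHRF1, a factor in maintenance of DNA methylation, fell 2.14-fold and the uracil glycosylase gene UNG 1.98-fold. For the flap endonuclease FEN1 the brighter probe rose 1.25-fold, a call lost without either control array, while another probe fell. In the mitosis and G2/M list 13 of 50 fell and 1 rose (12 and 1 adjusted over the list alone, adjusted p = 0.0208, and adjusted p = 0.305 with an estimated correlation), with TACC3 1.96-fold and the proliferation marker MKI67 1.92-fold lower. That list did not pass on the mean of a gene's probes (adjusted p = 0.0793).

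Cholesterol biosynthesis genes, the targets of SREBP2, fell with betulinic acid in 12 of 25 cases and rose in 1 (13 and 1 adjusted over the list alone, median log2 -0.35, adjusted p = 0.00115, and adjusted p = 0.298 with an estimated correlation). ACAT2 fell 1.87-fold and TMEM97, a sterol-regulated membrane protein gene, 1.79-fold, while HMGCS1 stood at log2 -0.09 ± 0.08. In the immediate early and AP-1 list 10 of 32 fell and 5 rose (11 and 5 adjusted over the list alone, adjusted p = 0.0208, and adjusted p = 0.298 with an estimated correlation). EGR3 fell 3.57-fold and EGR1 2.68-fold, and JUN rose 1.58-fold, a call lost without either control array. Proteasome genes fell in 14 of 35 cases and rose in 1 (14 and 3 adjusted over the list alone, adjusted p = 0.0208, and adjusted p = 0.298 with an estimated correlation), with PSMA2 1.65-fold lower, a call that either control array decided. Without the dimmest 50% of probes neither of the last 2 lists passed (adjusted p = 0.0831 for the immediate early genes and 0.0599 for the proteasome). Heat shock genes fell in 10 of 21 cases and rose in 2 (12 and 2 adjusted over the list alone, adjusted p = 0.0289, and adjusted p = 0.298 with an estimated correlation). STIP1, a cochaperone gene, fell 1.63-fold and DNAJB1 rose 1.98-fold, and without control replicate 1 the list did not pass (adjusted p = 0.0534).

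With fluorinated betulinic acid SLC7A11 rose 28.0-fold (log2 4.81 ± 0.08), HMOX1 26.0-fold (log2 4.70 ± 0.07), and INHBE, an inhibin subunit gene under ATF4 control, 25.6-fold. DDIT3 rose 18.9-fold, DNAJB9, a cochaperone of the endoplasmic reticulum, 13.1-fold, and the transcription factor gene ATF3 10.9-fold. GJA1 fell 26.5-fold (log2 -4.73 ± 0.10), IGFBP5 16.5-fold, and CA9, carbonic anhydrase 9, 12.6-fold. The replication genes GINS2 and PCNA fell 9.73-fold and 8.20-fold, and ESR1 fell 5.68-fold (log2 -2.51 ± 0.14). The mean signal of INHBE (log2 6.85) and BIRC3 (6.79) in the controls lay in the dimmest 25% of all values (below 7.62), as did that of GJA1 (6.70), GKN2 (6.92), GABRP (7.08), TSPAN2 (7.33) and SYNE1 (7.47) with the fluorinated form. Signal over background was not assessed, so every fold printed for these genes against such a group is of uncertain size.

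The remaining large rises with the fluorinated form above the median signal were of MT1X (19.1-fold), the microtubule protein gene MAP1B (14.4-fold), the cytokine gene LTB (13.9-fold), GADD45A (12.7-fold), SERPINA3 (12.3-fold) and the glutathione-degrading enzyme gene CHAC1 (9.32-fold). The remaining large falls were of CALML5 (13.6-fold), NPY1R (10.6-fold), SYNE1 (10.3-fold), CXCL12 (9.79-fold), PLEKHS1 (6.67-fold), UHRF1 (6.45-fold) and TMEM164 (6.38-fold), and the dimmer GKN2 fell by an uncertain amount (7.70-fold as measured). On the mean of a gene's probes IGFBP5 was at log2 -2.47, MAP1B at 3.07 and PLEKHS1 at -2.07. None of the genes taken by the size rule in this comparison lost its call in an alternative that gave it a value.

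In all, 7706 of 14888 genes changed with the fluorinated form, 4173 upward and 3533 downward (limma, adjusted as above). Of these, 1365 changed at least 2-fold, 740 upward and 625 downward. Olfactory receptor genes, expected to have little use in these cells, passed in 40.1% of 187 cases, against 51.9% of the other genes. Where a changed gene had a further probe that also changed, that probe went the other way in 267 of 1372 cases. On the values as deposited, whose median over all probes lay -0.18 on the log2 scale from the control, 7812 genes changed, 3028 upward and 4784 downward, and at 2-fold and above 496 rose and 883 fell. The share of rises was 54.2% after normalization and 38.8% as deposited, so directions are relative to the signal distribution of each array. The total was 4789 without control replicate 1 and 4739 without control replicate 2.

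Of 47 genes for G1/S and DNA replication 43 fell and 3 rose, also when adjusted over the list alone (median log2 -1.30, adjusted p = 4.28e-15, and adjusted p = 0.122 with an estimated correlation). CDC6, a licensing factor for replication, rose 1.33-fold, a call lost on the values as deposited and without control replicate 1, control replicate 2 or fluorinated betulinic acid replicate 2. FEN1 rose 1.32-fold on its brighter probe and fell on another (log2 -0.62 on their mean). Of 50 mitosis genes 20 fell and 8 rose, also when adjusted over the list alone (adjusted p = 0.0146, and adjusted p = 0.294 with an estimated correlation). MYBL2, a cell cycle transcription factor gene, fell 3.09-fold and MKI67 1.76-fold, while NDC80 rose 1.58-fold and HMMR 1.75-fold. CDKN1A rose 2.08-fold and CCND1, the gene of cyclin D1, fell 1.56-fold. Estrogen receptor targets fell in 27 of 38 cases and rose in 3 (28 and 3 adjusted over the list alone, median log2 -1.56, adjusted p = 1.19e-07, and adjusted p = 0.122 with an estimated correlation). TFF1, trefoil factor 1, fell 3.28-fold, while AGR2, a protein disulfide isomerase gene, rose 5.19-fold.

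In the ATF4 list 28 of 31 genes rose with the fluorinated form and none fell, also when adjusted over the list alone (median log2 1.42, adjusted p = 1.48e-13, and adjusted p = 0.137 with an estimated correlation). Chaperones of the endoplasmic reticulum and other genes of the unfolded protein response rose in 17 of 25 cases and fell in 1 (18 and 1 adjusted over the list alone, adjusted p = 0.000317, and adjusted p = 0.140 with an estimated correlation). SEC24D, a coat protein gene, rose 7.12-fold, and XBP1, the transcription factor of this response, fell 1.76-fold. NRF2 targets rose in 19 of 27 cases and fell in 2, also when adjusted over the list alone (adjusted p = 0.000317, and adjusted p = 0.140 with an estimated correlation), with PRDX1 2.43-fold lower. SLC7A11 is counted in this list and in the ATF4 list. The p53 list had 14 of 33 rises and 3 falls (14 and 4 adjusted over the list alone, adjusted p = 0.00358, and adjusted p = 0.140 with an estimated correlation), led again by SESN2 (6.33-fold) and GDF15 (5.94-fold). Metallothionein and zinc response genes rose in 6 of 9 cases, also when adjusted over the list alone (adjusted p = 0.00699, and adjusted p = 0.294 with an estimated correlation), with MT2A 9.15-fold higher. NF-kB and inflammatory targets rose in 15 of 28 cases and fell in 5, also when adjusted over the list alone (adjusted p = 0.0179, and adjusted p = 0.208 with an estimated correlation). BIRC3, an inhibitor of apoptosis, rose (5.74-fold from a dim control signal, so of uncertain size) and the chemokine gene CXCL3 fell 2.19-fold, and the list did not pass with the dimmest 50% of probes left out (adjusted p = 0.0765).

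Ribosome biogenesis and MYC target genes rose in 24 of 38 cases with the fluorinated form and fell in 5, also when adjusted over the list alone (median log2 0.47, adjusted p = 0.00227, and adjusted p = 0.140 with an estimated correlation). ODC1, ornithine decarboxylase, rose 2.59-fold and PPAN 2.53-fold. Oxidative phosphorylation genes fell in 29 of 67 cases and rose in 4, also when adjusted over the list alone (median log2 -0.22, adjusted p = 0.000584, and adjusted p = 0.140 with an estimated correlation). SDHC, a subunit of complex II, fell 2.05-fold and NDUFB6, of complex I, 2.01-fold. Heat shock genes fell in 12 of 21 cases and rose in 3, also when adjusted over the list alone (adjusted p = 0.0179, and adjusted p = 0.247 with an estimated correlation). HSPA1B fell 1.87-fold and the factor gene HSF1 rose 2.11-fold, and the list did not pass on the values as deposited (adjusted p = 0.0648). With the fluorinated form the cholesterol list (adjusted p = 0.223), the immediate early list (adjusted p = 0.0626) and the proteasome list (adjusted p = 0.208) did not pass. The immediate early list did pass on the values as deposited (adjusted p = 0.0167) and without control replicate 1 (0.0323) or control replicate 2 (0.0409).

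Set directly against betulinic acid at the same dose and time, the fluorinated form left HMOX1 11.9-fold higher (log2 3.57 ± 0.07), DNAJB9 7.76-fold, AGR2 7.65-fold, MAP1B 7.61-fold and LTB 6.72-fold. CALML5, a calmodulin-like gene of epithelia, was 9.47-fold lower (log2 -3.24 ± 0.13), GINS2 6.02-fold, CA9 5.87-fold, NDRG1 4.91-fold and PCNA 4.86-fold. ESR1 was 3.47-fold lower and TFF1 2.31-fold lower. DDIT3 was 4.92-fold higher and ATF3 6.06-fold higher.

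The other large differences upward above the median signal were in GADD45A (6.40-fold), LARP6 (6.07-fold), the NRF2 target OSGIN1 (5.66-fold), SERPINA3 (5.31-fold), LRRC49 (5.25-fold) and RASD1 (5.23-fold). Downward they were in TMT1A (5.00-fold), the adhesion molecule genes CEACAM6 (4.72-fold) and CEACAM7 (4.43-fold), BCAS1 (4.53-fold), CXCL17 (4.51-fold), IGFBP5 (4.33-fold) and SPOCK1 (4.31-fold). Genes lower at a dimmer signal, by amounts that are uncertain, were GJA1 (7.26-fold as measured), GABRP (4.90-fold), TSPAN2 (4.75-fold) and SYNE1 (4.44-fold). Without either fluorinated betulinic acid array another probe represented LARP6, at log2 1.01 and 0.92, and on the mean of its probes IGFBP5 was at -1.27. Some genes that moved with both compounds showed no passed difference. MT2A differed by log2 -0.08 (95% interval -0.29 to 0.13), PDZK1 by -0.03 (-0.20 to 0.14), TNFAIP2 by -0.03 (-0.22 to 0.16), CCND1 by -0.01 (-0.18 to 0.15) and MKI67 by 0.12 (-0.15 to 0.40). TSC22D3 was 1.90-fold lower with the fluorinated form than with betulinic acid.

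**Figure D1:**
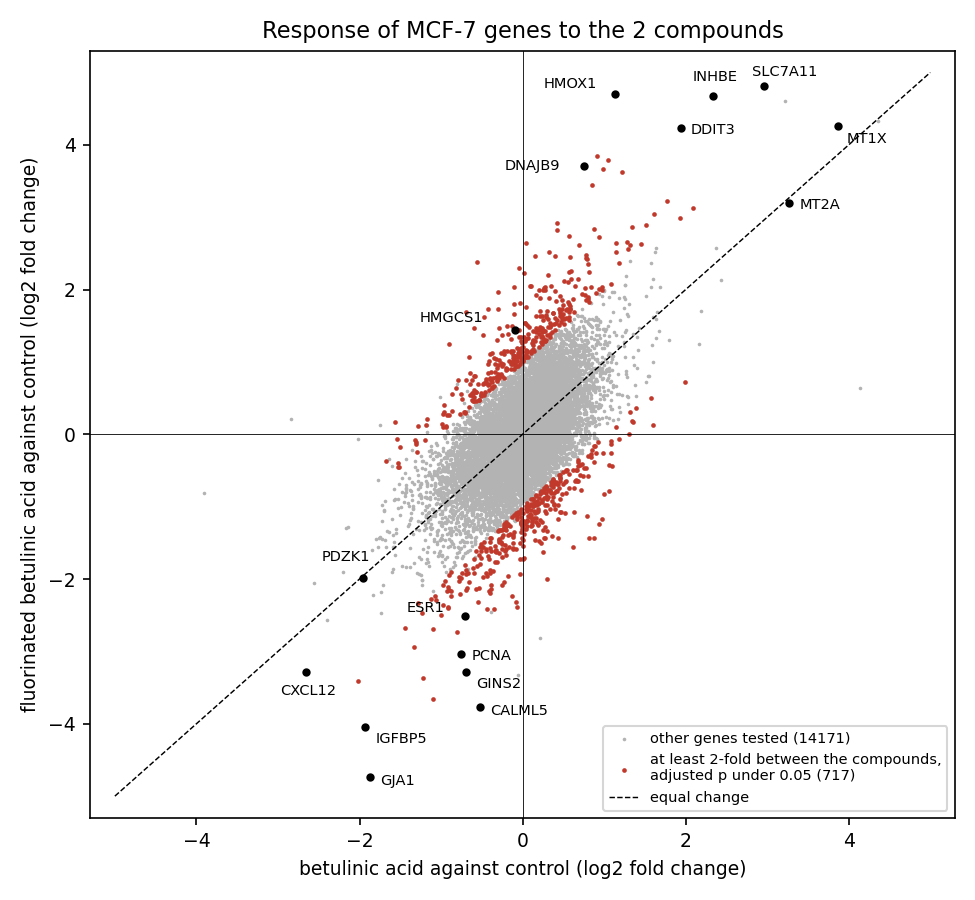
Each point is 1 of 14888 genes, with its log2 fold change for betulinic acid against control on the x axis and for fluorinated betulinic acid against control on the y axis, 717 genes at least 2-fold apart between the compounds in red, named genes in black and the dashed line at equal change. HMOX1 lies at 1.13 and 4.70, PCNA lies far below the line, and PDZK1 lies on it.

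Between the compounds 6635 of 14888 genes differed, 3387 higher and 3248 lower with the fluorinated form, and 717 differed at least 2-fold, 356 higher and 361 lower (limma, adjusted as above). As deposited, 6939 differed, 2290 higher and 4649 lower, so the share higher was 33.0% instead of 51.0%. At 2-fold and above, 228 were higher and 578 lower on the deposited values. Where a gene that differed had a further probe that also differed, that probe went the other way in 219 of 1050 cases. Without fluorinated betulinic acid replicate 2, 4094 genes differed.

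By the set test 9 lists differed between the compounds. Replication genes were lower with the fluorinated form in 38 of 47 cases and higher in 1 (40 and 1 adjusted over the list alone, median log2 -0.92, adjusted p = 2.11e-12, and adjusted p = 0.137 with an estimated correlation). The exception was CDC6 (1.98-fold higher). ATF4 targets were higher in 24 of 31 cases and lower in 2 (27 and 2 adjusted over the list alone, median log2 0.66, adjusted p = 1.60e-08, and adjusted p = 0.137 with an estimated correlation). NRF2 targets were higher in 15 of 27 cases and lower in 3 (17 and 3 adjusted over the list alone, adjusted p = 0.00111, and adjusted p = 0.137 with an estimated correlation). Estrogen receptor targets were lower in 23 of 38 cases and higher in 5 (24 and 5 adjusted over the list alone, adjusted p = 0.00031, and adjusted p = 0.137 with an estimated correlation), with CTSD, the cathepsin D gene, 2.88-fold lower.

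In 5 of these lists the medians against control lay on either side of 0 for the compounds. With betulinic acid the median was -0.35 for cholesterol biosynthesis and -0.29 for immediate early genes. It was close to 0 and the set test was not passed for the unfolded protein response (median -0.03, adjusted p = 0.550), oxidative phosphorylation (median 0.03, adjusted p = 0.823) and ribosome biogenesis (median -0.10, adjusted p = 0.187), so no opposite change is shown for these. Genes of the unfolded protein response were higher with the fluorinated form in 18 of 25 cases and lower in 1, also when adjusted over the list alone (median log2 difference 0.62, adjusted p = 3.74e-06, and adjusted p = 0.137 with an estimated correlation). MANF, a secreted factor of the endoplasmic reticulum, fell 1.86-fold with betulinic acid and was 4.43-fold higher with the fluorinated form than with betulinic acid. Cholesterol biosynthesis genes were higher with the fluorinated form in 14 of 25 cases and lower in 3 (16 and 3 adjusted over the list alone, median log2 difference 0.52, adjusted p = 0.000822, and adjusted p = 0.268 with an estimated correlation). HMGCS1, the synthase before HMG-CoA reductase, was 2.90-fold higher and CYP51A1, lanosterol demethylase, 2.75-fold higher. Immediate early genes were higher in 18 of 32 cases and lower in 1, also when adjusted over the list alone (adjusted p = 0.000198, and adjusted p = 0.137 with an estimated correlation), with PHLDA1 3.65-fold and KLF6 3.39-fold higher (log2 1.14 on the mean of its probes) and FOS 1.70-fold lower. Ribosome biogenesis genes were higher in 21 of 38 cases and lower in 3 (22 and 3 adjusted over the list alone, adjusted p = 0.000213, and adjusted p = 0.137 with an estimated correlation), with RRP9 2.21-fold higher. Oxidative phosphorylation genes were lower in 33 of 67 cases and higher in 6 (37 and 7 adjusted over the list alone, adjusted p = 0.000762, and adjusted p = 0.138 with an estimated correlation), with ATP5MG 2.14-fold lower.

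**Figure D2:**
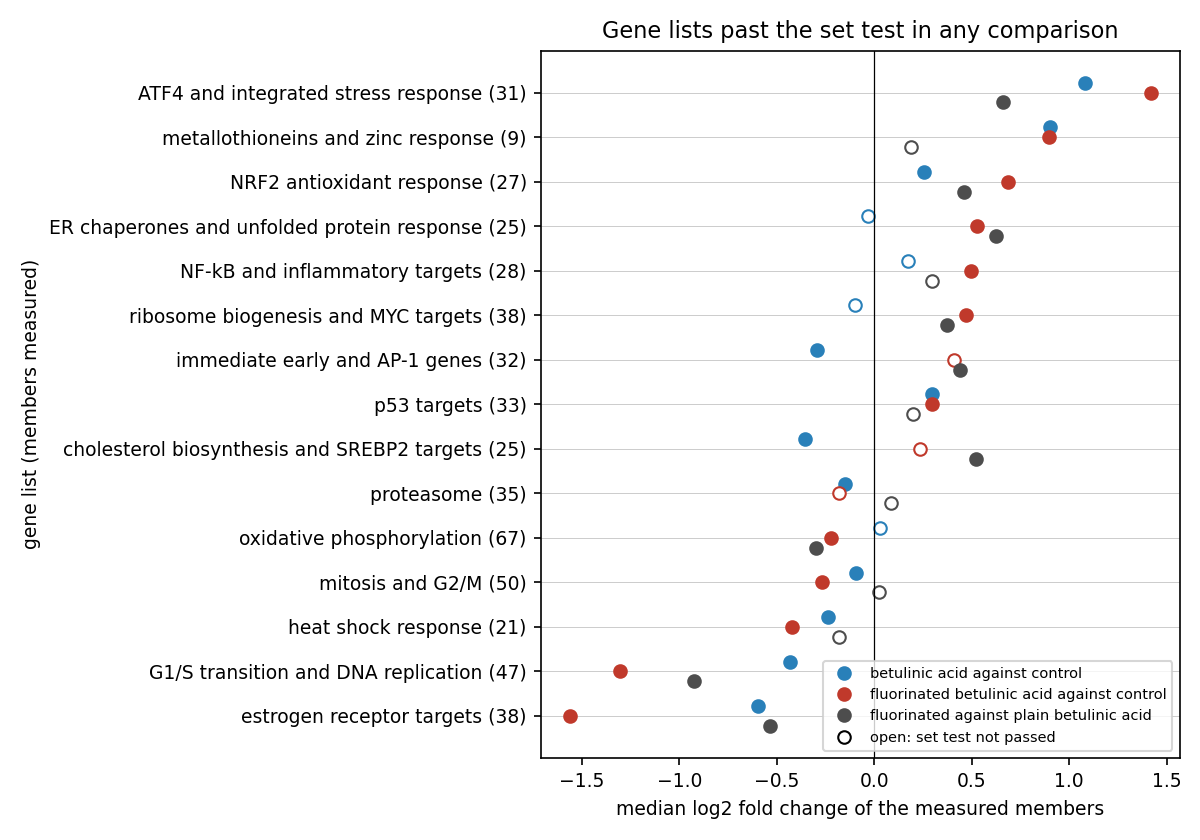
Median log2 fold change (x axis) of the measured members of the 15 gene lists that passed the set test in at least 1 comparison (y axis, members measured in brackets), coloured by comparison, with open circles where the test was not passed. Estrogen receptor targets lie at -0.59 with betulinic acid and -1.56 with the fluorinated form, and cholesterol biosynthesis genes lie at -0.35 and 0.23.

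**Figure D3:**
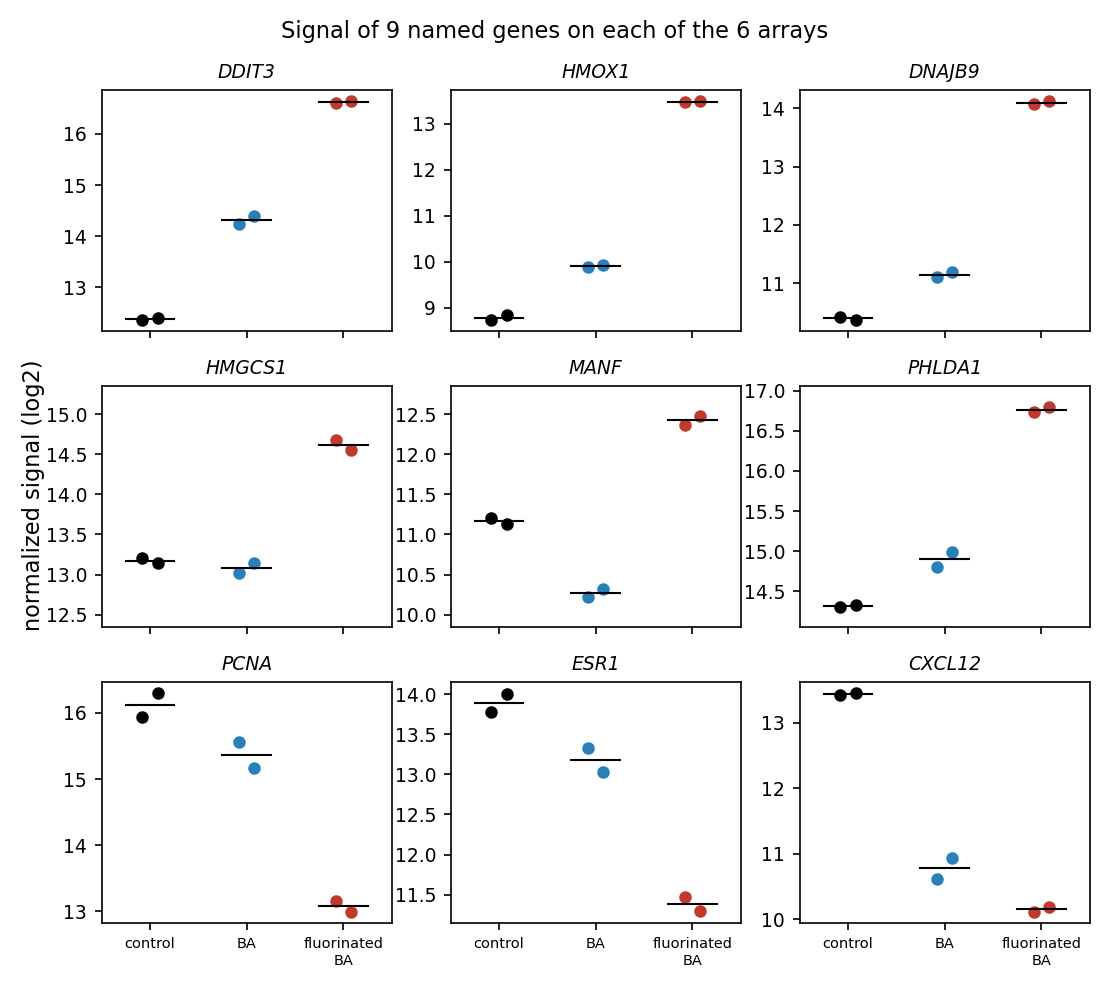
Normalized log2 signal (y axis) of 9 named genes on each of the 6 arrays by group (x axis, BA standing for betulinic acid), with points for arrays and lines for group means, and a separate y range for each gene. PCNA fell 8.20-fold with the fluorinated form, and MANF fell 1.86-fold with betulinic acid.

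The Sp transcription factors were among the genes chosen for betulinic acid before the data were examined. SP1 was at log2 -0.03 ± 0.07 with betulinic acid (95% interval -0.21 to 0.14) and 0.10 ± 0.07 with the fluorinated form, and neither passed. SP3 was at 0.15 ± 0.06 with betulinic acid and rose 1.26-fold with the fluorinated form, a call lost without either control array and on the mean of its probes (log2 0.16, adjusted p = 0.0840). SP4 was at -0.32 ± 0.11 with betulinic acid, which passed only without betulinic acid replicate 2 (log2 -0.47, adjusted p = 0.0161), and rose 2.06-fold with the fluorinated form, a difference of 2.58-fold between the compounds (adjusted p = 0.00132). BAX fell 1.28-fold with betulinic acid on its brighter probe (adjusted p = 0.0411), another probe changed the other way, and the call was lost in most leave-out settings and under other scalings. Probes of BCL2 were among the dimmest 25%, and LDLR and TP53 were not analysed here.

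The list of Sp-regulated genes was among 21 lists that passed in no comparison by camera with the preset correlation (adjusted p from 0.0555 to 0.988). These covered fatty acid synthesis, LXR targets, fatty acid oxidation, cell cycle inhibitors with D cyclins, the BCL2 family, luminal markers, epithelial-mesenchymal transition, the interferon response, hypoxia, glycolysis, mitochondrial and cytosolic ribosomal proteins, autophagy, xenobiotic metabolism, replication-dependent histones and TGF-beta targets. They also covered markers of fibroblasts, leukocytes, endothelium and basal epithelium. Among these markers the endothelial gene CDH5 rose 2.12-fold with betulinic acid, a call lost without control replicate 2, and was 2.53-fold lower with the fluorinated form than with betulinic acid. SFN, a basal marker, fell 1.60-fold with each compound, and the leukocyte gene ITGAM fell 1.43-fold with the fluorinated form, a call lost without control replicate 1. FAP, a fibroblast marker, rose 1.45-fold with the fluorinated form. Of the 21 lists, autophagy passed with betulinic acid by camera on ranks (adjusted p = 0.0478).

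Across the 14888 genes, which are not independent replicates, the log2 changes of the compounds against the shared controls correlated at r = 0.602. Groups simulated without any effect against the same controls gave r = 0.50. Sharing controls fixes that value for groups without effect, whatever the size of the noise, so it is no baseline for the observed r. The covariance was 0.164, against 0.0113 simulated, a difference of 0.152. Rises with both compounds numbered 1841 genes, where independent lists would share 796, and falls with both numbered 1277, where independent lists would share 505. Simulated groups without effect shared at most 1 call. Without effects few genes are called in either comparison, so that count does not show how many calls the shared controls add. Part of the excess in shared calls may come from the shared controls. With 1 control array for each compound, so that none was shared, r was 0.533 and 0.529 and the covariance 0.151 and 0.152 for the 2 ways of dividing the controls, a test chosen after the data were seen. Of the 337 genes changed at least 2-fold by betulinic acid, 268 changed the same way with the fluorinated form. By the direct test 83 of the 337 went further with the fluorinated form and 107 changed less or the other way. The others showed no passed difference. The 337 were picked for a large change on the betulinic acid arrays, which the direct test uses again. That choice favours a smaller change with the fluorinated form, so the 2 counts do not show which is more common.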

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

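Both tests of the cholesterol pattern were chosen before the results of the tests were seen, though after the pattern itself. The 5 gene lists are given here because the test between the compounds passed while their medians against control lay on either side of 0. With betulinic acid 3 of these medians were close to 0 and did not pass the set test, at -0.03 for the unfolded protein response, 0.03 for oxidative phosphorylation and -0.10 for ribosome biogenesis. For cholesterol biosynthesis the median log2 difference between the compounds was 0.521, with -0.35 for betulinic acid and 0.23 for the fluorinated form, and only the first of these passed the set test. The lowest median difference over quantile normalization, median centring and the deposited values was 0.440. The shift between the compounds' deposited medians (-0.16) ran the other way from this difference and was smaller. Keeping or removing such a shift could not undo the difference. Its survival after centring and on the deposited values is therefore no evidence about scaling. Centring does no more than remove that shift, so the test could not reach other faults of scaling. The median with the fluorinated form against control did vary, from 0.101 as deposited to 0.277 after centring. A single deviating array is argued against, since the lowest median difference with each array left out was 0.465. A difference between the compounds in the sterol response remains a hypothesis, found and tested on these same arrays, and it did not pass with an estimated correlation (adjusted p = 0.268). Whether each group's arrays came from 1 culture stays open, so a difference between single cultures was not tested.

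The median difference between the compounds was 0.625 for the unfolded protein response, 0.442 for immediate early genes, 0.372 for ribosome biogenesis and -0.296 for oxidative phosphorylation. Among 3913 tested probes without a gene name, which no comparison of genes used, 227 changed at least 2-fold with the fluorinated form.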

How the results depend on the processing

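Counts of changed genes stayed within 1.5 times of those reported, apart from the settings given here. Leaving out each array gave 1060 to 4554 changed genes for betulinic acid, 4739 to 8368 for the fluorinated form and 4094 to 6552 between the compounds. The lowest values came without control replicate 2 (1174 and 4789 without control replicate 1) and, between the compounds, without fluorinated betulinic acid replicate 2. A lone array left in a group is assumed to vary like the others. Counts at 2-fold and above ranged from 282 to 429, 1358 to 1506 and 660 to 941, and the correlation of the compounds' changes from 0.525, without betulinic acid replicate 2, to 0.628. It was 0.533 and 0.529 with 1 control array for each compound, chosen after seeing the data. Camera with an estimated correlation passed 0 lists in each comparison, where 3, 8 and 8 had an unadjusted p under 0.05, and camera on ranks passed 12, 12 and 9. With fry, which does not compare a list with other genes, 29, 26 and 26 passed. A correlation above the preset 0.01 does not account for every loss. For estrogen receptor targets the estimate was -0.0124, yet camera's unadjusted p with betulinic acid rose from 6.52e-10 to 0.00545. For ribosome biogenesis it was -0.0199, and p with the fluorinated form rose from 0.000441 to 0.0260. Some other lists had a higher estimate, such as 0.0510 for ATF4. Camera also takes p from the 3 residual degrees of freedom with an estimated correlation, and from the much larger number of genes with a preset one. How much of each loss this makes up was not tested.

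Deviations of arrays with the same replicate number correlated between groups at -0.07, -0.05 and -0.01, so no shared replicate effect was seen. Whether the arrays were paired by culture or handling is not given. With a replicate block 4508, 7441 and 6238 genes changed. On the mean of a gene's probes, which brings in probes that disagree, BAX was at log2 0.14 with betulinic acid and -0.27 between the compounds, FEN1 at -0.18 and -0.62 with the 2 compounds, and TXN at 0.11 with the fluorinated form, each the other way from its brightest probe. Leaving out probes whose 2 arrays differed by over 1, chosen after seeing the data, put NEUROD2 on another probe at 0.23 with betulinic acid. Among the named genes, the calls lost with the direction kept numbered 43 without control replicate 1, 49 without control replicate 2, and at most 30 in any other setting, besides the turned values above. No probe was tested against a background level, so signal over background was not assessed.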

Other observations

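Families formed from the letters that begin a symbol were tested after the data were seen, over 265 families of at least 8 tested genes. Subunits of the mitochondrial inner membrane import machinery (TIMM genes) were higher with the fluorinated form than with betulinic acid in 11 of 14 cases and lower in none, with a median log2 difference of 0.49 (camera adjusted p = 0.0392, and adjusted p = 0.990 with an estimated correlation). It was 0.34 on the values as deposited. Against control the median was -0.14 with betulinic acid and 0.04 with the fluorinated form (-0.05 as deposited), and neither passed (adjusted p = 0.552 and 0.841). TIMM10 differed by 0.95 ± 0.08 and TIMM9 by 0.72 ± 0.07. Semaphorins, guidance ligands found on many cell types, were lower in 9 of 15 cases and higher in none (median -0.46, adjusted p = 0.0382, and adjusted p = 0.990 with an estimated correlation), and stood at -0.64 as deposited. SEMA5A differed by -1.77 ± 0.06 and SEMA3F by -1.37 ± 0.15. Genes with MCM symbols, which include the minichromosome maintenance genes of DNA replication, were lower in 10 of 10 cases (median -1.0, adjusted p = 3.88e-05, and adjusted p = 0.990 with an estimated correlation). The function of each member was not checked. These examples were chosen after their values were seen. Zinc finger genes with ZNF symbols rose with the fluorinated form against control in 168 of 372 cases and fell in 53 (median 0.22, and 0.08 as deposited, adjusted p = 0.0444, and adjusted p = 0.992 with an estimated correlation).

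Genes with olfactory receptor symbols, expected to have little use in these cells, had a median signal of 9.67 on the log2 scale, against 10.98 for all tested genes, and 187 were tested. Of these, 32 changed with betulinic acid, 75 with the fluorinated form and 49 between the compounds. The shares were 17.1%, 40.1% and 26.2%, against 33.6%, 51.9% and 44.8% of the other genes. At 2-fold and above there were 4, 9 and 2 olfactory receptor genes. Those shares were 2.14%, 4.81% and 1.07%, against 2.27%, 9.22% and 4.86% of the other genes, so with betulinic acid the shares at this size were about alike.

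The comparison of the variation of single genes and both tests of the lower signal were chosen only after the results were seen. PLA2G2E, HRH3 and NEUROD2, genes known from other tissues, were among the 12 largest falls with betulinic acid above the median signal. The median change of olfactory receptor genes with betulinic acid was -0.0205 after quantile normalization. That step gives all arrays one distribution and can remove a general fall of dim probes. The value therefore does not decide whether unused probes fell. As deposited, the 10th percentile of the betulinic acid arrays lay at log2 -0.087 and -0.418 from the controls. The median spread within groups of those receptor genes was 1.06 times that of genes of like signal, with a bootstrap SD of 0.114, which does not decide whether unspecific signal varied between arrays. The median within-group spread of the 3 genes was 5.77 times that of genes of like signal. They were taken for arrays that did not overlap between control and betulinic acid, so the gaps between those arrays decide nothing. With the fluorinated form they were also lower, at log2 -2.05, -1.30 and -1.45 (limma adjusted p = 0.0126, 0.00541 and 0.0325). That comparison used the same control arrays, so it is no separate test. Variation of their spots stays open, as do a general fall of unused probes and a change of their transcripts.

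The deposited signal was lower on both fluorinated betulinic acid arrays. The shift against the controls varied by 0.194 and 0.585 over the 10th, 50th, 90th and 99th percentiles. On the betulinic acid arrays, which had medians near those of the controls, it varied by 0.104 and 0.430, so the values do not decide whether one scaling factor per array lowered the signal. The medians of both arrays lay below the lower control, by 0.20 and 0.121, beyond the 0.03 between the controls. This does not test a higher signal floor on 1 array, which would add signal and not lower a median. A treatment effect on total signal and a handling difference between groups were not tested.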
